A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

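Total RNA from a Halobacterium salinarum NRC-1 strain that lacks ura3 and vng2334c was compared with a common NRC-1 reference RNA on 8 spotted 2-colour arrays. The labels describe 4 cultures, 1 for each combination of high or low oxygen with light or dark. Each culture was hybridised on 2 arrays with the dyes exchanged, so that the knockout RNA carried Alexa 532 on 1 array and Alexa 647 on the other. Per the labels, high oxygen meant shaking at 210 RPM and low oxygen meant 100 RPM in a stoppered flask. Each flask of 125 mL held 50 mL of rich medium, and cells were taken in mid-log phase. The reference was a mid-log culture at an OD600 of 0.5 to 0.6.

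The deposited scanner files give the intensity of each spot and of its background in both dyes at a high and a low scanner setting, and per the file headers these intensity columns are not background-subtracted. The deposited Spot Confidence score was used only as a mark of saturation, because spots with a score under 100 at the high setting had a brightest pixel of 65535. The planned removal of flagged spots was therefore run as an alternative that leaves saturated spots out. The authors' value table holds log10 ratios. Its rows followed the position of the spots on the slide, and its columns correlated with the log10 ratio of Alexa 532 to Alexa 647 of the scanner files at r between 0.610 and 0.978, with slopes from 0.336 to 1.00. With the rows in the scanner's own spot numbering these correlations lay between 0.315 and 0.484. The sign of this relation was positive on all 8 arrays, so the authors' ratios were not turned for the dye exchange. The column medians of the log10 table were 0.0661, 0.0613, 0.0696, 0.135, 0.0847, 0.0806, 0 and 0.0693, in the order high oxygen with light, high oxygen in the dark, low oxygen with light and low oxygen in the dark, Alexa 532 before Alexa 647. How the authors centred and normalized these values is not given in the sources used here.

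The slide carried 10752 spots, which fell into sets of 4 spots of the same probe, a neighbouring pair on each of the 2 sides of the slide. This layout was inferred from the named spots, which all followed it. Spot sets that contained 1 of the 164 spots without a value in the authors' table were left out, which removed 115 sets and left 2573. The annotation supplied for these probes gave a gene symbol to 133 of the 2573 sets and none to the other 2440, and no probe carried several genes. Unnamed probes are given by a number that counts spot sets in the order of the authors' table. The gene table at hand describes another strain, holds no VNG locus tags and was not used for coordinates. VNG2334C was not among the named probes and its neighbours could not be placed, so these genes are not analysed here.

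High-setting spot means were corrected for background with normexp and an offset of 50, and log ratios were normalized within each array by loess with the unvalued spots at weight 0. Ratios were turned to knockout over reference from the labelled dyes. The 4 spots of a set were averaged, and then the 2 arrays of a culture, which are technical repeats of the same RNA. The analysis was run with limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Linear models with empirical Bayes moderation were fitted to the 4 culture values with terms for oxygen and light, which leaves 1 residual degree of freedom, and the moderation added 3.18. The intercept tested the mean ratio to the reference against 0. P-values were adjusted over the 2573 probes by the Benjamini-Hochberg method, with a threshold of 0.05. The oxygen-by-light difference has no residual degrees of freedom and was described by size only. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 where at least 4 members had a named probe, which was the case for 11 of 31 lists. By their name patterns, the list of retinal proteins also held the regulator gene bat and the proteasome list panB of pantothenate synthesis.

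Named genes were chosen by a rule fixed at the same time. For oxygen it took up to 15 probes each way, and for light up to 10, ranked by size among those with 1 sign in all 4 separate differences, given by 2 states of the other factor and 2 dye orientations. For the oxygen-by-light difference and for the ratio to the reference it took 5 each way, and for each list the members with the largest differences. Of the 30 probes ranked for oxygen 1 had a symbol, and of the 20 ranked for light none had, so the ranking was repeated among the 133 named genes. That restriction was chosen after the annotation had been seen. A probe counted as well above background on an array when the mean signal of its 4 spots exceeded the 95th percentile of the spots without a value. Those spots were taken as blanks or controls, which was an assumption, and most of the sets that held them also held spots with a value. The counts above background are therefore approximate. Ranked genes that were well above background on no array of a side, or were saturated there, are named without a value or given with a floor under the signal.

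The procedure was tested on simulated spots of 2573 probes with known changes. Limma recovered 54.5% of the 2-fold oxygen changes, 97.0% of the 4-fold and 100% of the 8-fold ones. For light it recovered 53.0%, 98.5% and 100%, and for the reference comparison 97.0%, 98.5% and 100%. In each comparison 66 probes were changed by 2-fold and 67 each by 4-fold and 8-fold. So many true changes ease the Benjamini-Hochberg threshold. A change in 1 or a few probes was not simulated and would meet a stricter threshold, so the shares do not apply to it. Dye and spot noise in the simulation was also milder than on the arrays, so these shares are upper limits. Alternatives covered background correction, normalization, dim and saturated spots, dye orientation, the variance model, the authors' table and the omission of each culture. The number of arrays and cultures limits the precision, since each combination of oxygen and light was represented by 1 culture.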

Results

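The transcriptome of an extreme halophile lacking ura3 and vng2334c was measured under 4 growth conditions. The series varied oxygen supply and illumination together, with 1 culture at high oxygen in the light, 1 at high oxygen in the dark, 1 at low oxygen in the light and 1 at low oxygen in the dark. Every culture was hybridised on 2 arrays against the same reference RNA with the dyes exchanged. The median background-subtracted signal per array ranged from 1078 to 3460 in Alexa 647 and from 1024 to 2839 in Alexa 532. Between 48.0% and 71.4% of the probes were well above background in Alexa 647, and between 41.0% and 84.8% in Alexa 532. The knockout RNA of 95 of the 133 genes with a symbol was well above background on all 8 arrays, and that of 5 on none. Log ratios of the 2 arrays of a culture correlated across probes at r = 0.046, -0.36, -0.17 and -0.15 for high oxygen in light, high oxygen in the dark, low oxygen in light and low oxygen in the dark. Values below are log2 ratios or log2 differences with the standard error of the limma fit over 4 cultures. The 1 residual degree of freedom of that fit is the oxygen-by-light difference of the culture values, moderated over all probes. The error therefore does not measure the spread between arrays or between repeat cultures.

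The first comparison set the knockout strain against the reference. It did not check the deletions, since vng2334c had no named probe. The symbol ura3 was absent from the annotation, and pyrF, which encodes the orotidine monophosphate decarboxylase of pyrimidine synthesis and is the usual counterpart of ura3, stood in for it. pyrF was the lowest of the 133 named genes, 1.55-fold below the reference (log2 -0.63 ± 0.15). Its culture values were 0.03 at high oxygen in light, -0.51 at high oxygen in the dark, -1.28 at low oxygen in light and -0.77 at low oxygen in the dark, and it was lower on 7 of 8 arrays. Its knockout signal was well above background on 3 of the 8 arrays and its reference signal on 5, and whether the probe lies inside the deleted part is not known. phoU, a regulator of phosphate uptake, was lower by nearly the same amount at -0.63 ± 0.09, on 8 of 8 arrays and in all 4 cultures, from -0.90 at low oxygen in light to -0.53 at high oxygen in light. Limma gave adjusted p = 0.319 for pyrF and 0.229 for phoU, so neither passed the threshold over all probes.

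hisA of histidine synthesis (-0.40 ± 0.07) and argH, the argininosuccinate lyase of arginine synthesis (-0.38 ± 0.07), were lower than the reference. Single arrays of hisA ran from -1.04 to 0.19, which its error does not show. On the other side stood carB, the large subunit of carbamoyl phosphate synthetase (0.39 ± 0.09), the glutamate dehydrogenase gene gdhA1 (0.31 ± 0.08), truA of tRNA pseudouridylation (0.29 ± 0.19) and the citrate synthase gene citZ (0.25 ± 0.08). gatC, at 0.21 ± 0.31, was well above background in the knockout RNA on 1 array only, truA on 3 and hisA on 4, and hutI of histidine breakdown, also among the 5 lowest by rank, on none. Without the high oxygen light culture the value of truA was 0.0555. A single probe of 2573 passed the threshold in limma (308 at unadjusted p under 0.05, with 129 expected by chance). This was spot set 2217, IDs 4433, 4434, 9809 and 9810 of the authors' table, which has no symbol. It was 4.35-fold below the reference (log2 -2.12 ± 0.07, limma adjusted p = 0.0154) and lower on 8 of 8 arrays, with array values from -3.00 to -1.55. Its reference signal was well above background on 7 arrays and its knockout signal on 2, both at high oxygen. At low oxygen the knockout signal was above background on 0 of 4 arrays. On the dark array with the knockout in Alexa 532 the reference signal was not above it either. With a floor under the knockout signal, the reference was 3.60-fold brighter at low oxygen. This figure sets the mean reference signal, after quantile normalization of the spot intensities, against the higher of the probe's own knockout signal and the lowest knockout signal among probes above background. That floor is not a detection limit, so the figure is no strict bound. At high oxygen the floor left the knockout value unchanged, although the signal was above background on only 2 of 4 arrays. The ratio stayed negative in every alternative that kept the probe, but its call ended with median centring, with low-setting values for saturated spots, with Alexa 647 arrays alone, and when the high oxygen dark culture or either low oxygen culture was left out.

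With the dimmest 25% of the probes left out, 123 of 1929 probes passed, 53 higher and 70 lower than the reference, against 1 in the full set. Among them were 11 genes with a symbol. Their ratios were the same as in the full set, since only the moderation and the number of probes tested changed. The calls are thus no further measurement. The limma adjusted p in this smaller set was 0.00384 for phoU, 0.0125 for hisA, 0.0152 for argH, 0.0153 for pyrF, 0.0259 for carB and 0.0354 for gdhA1. The other 5, named after their values were seen, were all lower in the knockout. They were serB of serine synthesis at -0.36, purL of purine synthesis at -0.35, the serine hydroxymethyltransferase gene glyA at -0.34, panB of pantothenate synthesis at -0.33 and the prephenate dehydratase gene pheA at -0.31, each on at least 7 of 8 arrays. The reference was not a parental culture grown alongside, so these ratios mix the deletions with the difference between cultures. All arrays shared this 1 reference RNA, so the errors and p-values against it leave out its own spread.

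**Figure D1:**
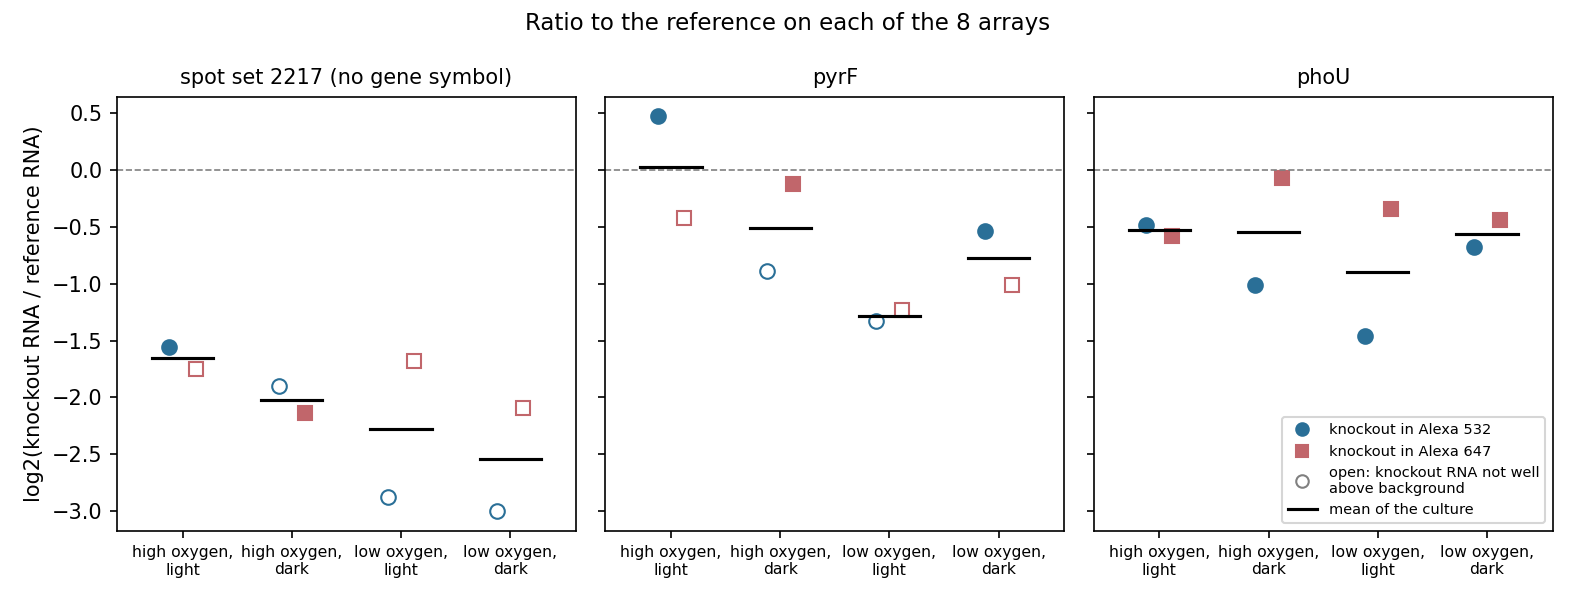
Log2 ratio of knockout to reference RNA on each array for spot set 2217, pyrF and phoU, by culture on the x axis. Circles have the knockout in Alexa 532 and squares in Alexa 647, open symbols mark arrays where the knockout RNA was not well above background, and bars are culture means. All 8 values of spot set 2217 and of phoU lie below 0, as do 7 of 8 for pyrF.

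The second comparison asked how the oxygen supply changed transcript levels in this strain. In the named set, 14 genes kept 1 sign in both light states and both dye orientations, where chance gives 16.6, and 12 of these were measured at both oxygen levels. Lower at low oxygen were htr18, a transducer of the chemotaxis system (-0.60 ± 0.21), trpC of tryptophan synthesis (-0.52 ± 0.23), the mevalonate kinase gene mvk of isoprenoid lipid synthesis (-0.39 ± 0.16), moaC of molybdenum cofactor synthesis (-0.33 ± 0.16) and glmS of glucosamine synthesis (-0.31 ± 0.17). Smaller values in the same direction were found for sucC, a subunit of succinyl-CoA synthetase (-0.20 ± 0.15), the methionine sulfoxide reductase gene msrA (-0.18 ± 0.15) and ppsA, which acts in gluconeogenesis (-0.17 ± 0.15). Higher at low oxygen were pan1, the ATPase that feeds the proteasome (0.42 ± 0.16), citZ (0.24 ± 0.16), the transducer gene htr8 (0.17 ± 0.15) and the methionine aminopeptidase gene map (0.14 ± 0.15). None of the 12 passed the threshold, with limma adjusted p from 0.940 to 0.960. In the authors' table pan1 was at 0.00822, trpC at -0.32, mvk at -0.18, glmS at -0.15 and map at 0.0575, and with 1 culture left out htr18 ranged from -0.96 to -0.23, trpC from -0.84 to -0.21, glmS from -0.44 to -0.18, mvk from -0.49 to -0.28 and map from 0.0555 to 0.233. htr18 was above background on 3 of 8 arrays and trpC on 2, and ppsA was saturated on 3, while hutI and hutU of histidine breakdown, also in the ranking, were not well above background on every array of at least 1 oxygen level and have no value here.

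Over all probes limma called 0 for oxygen, with 110 at unadjusted p under 0.05 against 129 expected by chance, 30 higher and 80 lower at low oxygen. The smallest adjusted p was 0.94. The typical 95% interval of a named gene reached 0.43 to either side of its difference, before any adjustment for the number of probes. One sign in all 4 differences was shown by 298 probes, where chance gives 322, and by 298 for the remaining way of splitting the 4 cultures into pairs, low oxygen in the dark and high oxygen in light against the others. Only 3 probes combined this with a mean of at least 2-fold, all lower at low oxygen, against 7 for that remaining split. The high oxygen light culture stood apart, with r from -0.03 to 0.14 with the other cultures, which correlated at 0.32 to 0.44 among themselves. The largest difference of these among probes without a symbol was in spot set 2300, which was not well above background in the knockout RNA on any array. pyrF passed in the authors' table at a limma adjusted p of 0.034 but not here (0.940), with its knockout RNA above background on 1 of 4 arrays at low oxygen and 1 of the 4 separate differences of opposite sign.

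**Figure D2:**
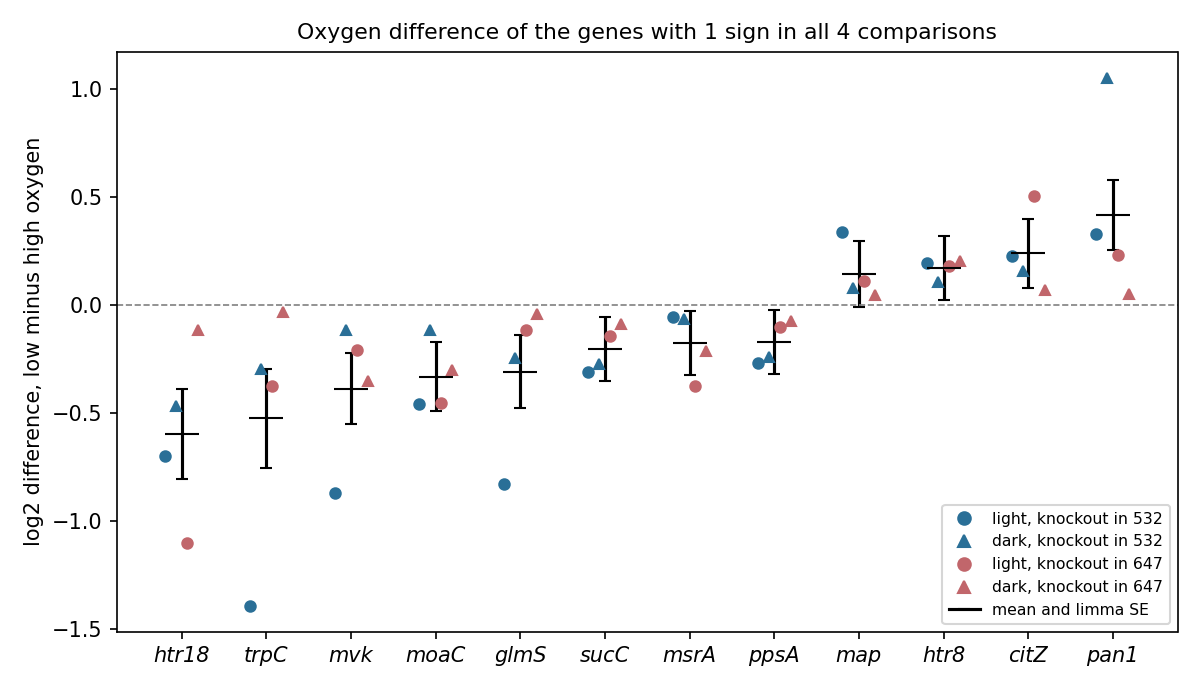
Log2 difference between low and high oxygen for the 12 named genes with 1 sign in all 4 separate differences, ordered by their mean. Coloured points are the differences in light and in the dark for each dye orientation, and black bars are the mean with its limma standard error. The means run from -0.60 for htr18 to 0.42 for pan1, and the dye orientations of a gene can differ by more than the mean itself.

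None of the 11 tested gene lists passed the threshold for oxygen. Of the 31 lists, 13 had no named probe and were not tested. Among these were gas vesicles, DMSO and TMAO respiration, terminal oxidases and electron carriers, and carotenoid and isoprenoid synthesis. The list of retinal proteins held no bacteriorhodopsin gene. Of the 11 chemotaxis and transducer genes 8 were lower and 3 higher at low oxygen, with a median of -0.08, cheB at -0.29 and htr7 at -0.28 beside htr18. In aromatic amino acid synthesis (median -0.22 over 4 genes) pheA lay at -0.17 and aroC at -0.12 besides trpC, while trpB was not well above background at low oxygen. In the citric acid cycle, with 6 members, citZ lay at 0.24, sucD at -0.26 and sucC at -0.20, and icd was saturated on 5 of 8 arrays and is given no value. The low oxygen cultures of sucD were uneven, at -0.40 in light and -0.12 in the dark. Of the retinal proteins, the sensory rhodopsins sop1 and sop2 lay at -0.06 and 0.16 and the halorhodopsin hop at -0.19. hop fell from 0.29 at high to -0.22 at low oxygen in light, but went from -0.04 to 0.10 in the dark. The retinal protein list had a median of -0.07 together with the regulator gene bat, which was not well above background at low oxygen. Medians were -0.01 for 12 aminoacyl-tRNA synthetases, where aspS reached 0.26, -0.01 for 12 purine and pyrimidine genes, 0.01 for glycerol and central carbon, -0.04 for the proteasome list, -0.08 for cobalamin synthesis, 0.03 for DNA repair and 0.05 for DNA replication, the last 5 with 4 members each. For aspS the low oxygen cultures lay at 0.46 in light and 0.18 in the dark. In DNA repair uvrB lay at 0.31 ± 0.21 and mutL, above background on 4 of 8 arrays, at -0.80 ± 0.35, and for both the high oxygen light culture (-0.35 and 0.75) lay far from the high oxygen dark one (0.06 and -0.15). No member passed limma's threshold over all genes, and 0 passed when adjusted over the list alone. The lowest camera adjusted p was 0.629, for aromatic amino acids, and 0.930 with an estimated correlation. For the synthetases, the purine and pyrimidine list, the proteasome and DNA repair the median, the mean and the test differed in sign.

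**Figure D3:**
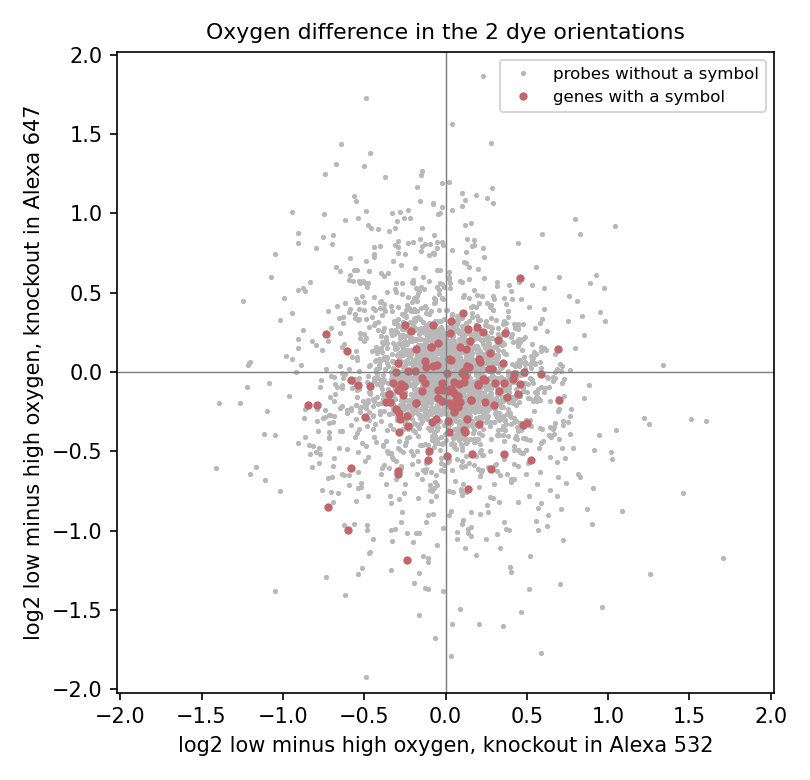
Oxygen difference (low minus high, log2) of 2573 probes, with the knockout RNA in Alexa 532 on the x axis and in Alexa 647 on the y axis, each the mean over light and dark. Red points are genes with a symbol. The orientations correlated across probes at r = -0.10, and at 0.21 across the 133 named genes.

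The third comparison asked what illumination changed. Among the named genes, 6 kept 1 sign in both oxygen states and both dye orientations, where chance gives 16.6. Lower in the dark were glpK, the glycerol kinase (-0.35 ± 0.15), the phenylalanyl-tRNA synthetase gene pheS (-0.28 ± 0.16), purE of purine synthesis (-0.19 ± 0.16), the nucleoside diphosphate kinase gene ndk (-0.10 ± 0.15) and sucC (-0.04 ± 0.15). The lysyl-tRNA synthetase gene lysS was higher in the dark by 0.10 ± 0.15. None passed, with a limma adjusted p of 1 for each. With 1 culture left out pheS ranged from -0.45 to -0.11, purE from -0.33 to -0.0554, ndk from -0.15 to -0.0432, lysS from 0.0287 to 0.16, sucC from -0.16 to 0.0698 and glpK from -0.46 to -0.23. ndk was saturated in the knockout RNA on 4 of the 8 arrays, and glpK was above background on 5.

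Limma called 0 probes for light, with 88 at unadjusted p under 0.05, 40 higher and 48 lower in the dark. One sign in all 4 differences was shown by 215 probes, below the 322 given by chance, and 3 of them reached 2-fold, all lower in the dark. The difference in the 2 dye orientations correlated at r = -0.30 across probes and at -0.52 across the named genes. With the authors' table in place of the scanner values 80 probes passed, 5 higher and 75 lower in the dark, 3 of them with a symbol. The median difference over all probes was then -0.093, against 0.000424 in the main fit, so a shift of all probes goes with this one-sided count.

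The list of retinal proteins, which are light-driven pumps and light sensors, did not pass and had a median of -0.02 together with the regulator gene bat, which was not well above background in light. sop2 had the largest value, -0.24 ± 0.15, beside sop1 at -0.04 and hop at -0.00. In the purine and pyrimidine list 9 of 12 genes were lower in the dark (median -0.08), including purF at -0.30 and purM at -0.25. The purM value leans on the low oxygen light array with the knockout in Alexa 532, at 0.69, while its other arrays lay between -0.46 and 0.06. purB, also lower, was not well above background in the dark and is given no value. Chemotaxis genes had a median of -0.01 with 8 of 11 lower, and htr18 lay at -0.42 and htr7 at 0.24. The htr18 value rests on the high oxygen light culture, at 0.70, while its other cultures lay between -0.31 and -0.02. For htr7 the low oxygen light arrays differed, at -0.79 with the knockout in Alexa 532 and -0.06 in Alexa 647. The other medians were 0.06 for the citric acid cycle, 0.01 for aminoacyl-tRNA synthetases, 0.02 for cobalamin, -0.08 for aromatic amino acids, -0.05 for glycerol and central carbon, 0.04 for the proteasome list, -0.15 for DNA repair and 0.08 for DNA replication. No member passed limma's threshold, and 0 passed adjusted over the list alone. The lowest camera adjusted p was 0.688, for purine and pyrimidine synthesis, and the lowest with an estimated correlation was 0.989. For the synthetases and the aromatic amino acid list the signs of median, mean and test differed.

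The last comparison asked whether the response to darkness depended on oxygen, as the dark minus light difference at low oxygen minus that at high oxygen. The DNA mismatch repair gene mutL had a value of 1.30, from a dark minus light difference of -0.89 at high oxygen and 0.40 at low oxygen. Its knockout RNA was above background on 4 of 8 arrays, 1 per culture, and the value was 0.14 in the authors' table. Values were negative for the cysteinyl-tRNA synthetase gene cysS (-0.64, with -0.21 in the Alexa 532 and -1.06 in the Alexa 647 arrays) and for the excision repair gene uvrB (-0.59, with -0.43 and -0.75 in the same order). The ranking also held gatC, purB, truA, nadC, hisD and uvrA, which were not well above background in at least 1 culture, and pyrI, which was saturated on 5 of 8 arrays, among them both arrays of the high oxygen dark culture. These differences have no test, since each condition was 1 culture. A value of at least 2-fold with the same sign in both orientations was found for 181 probes, 6 with a symbol, but for 1 of the 1176 probes above background on all arrays.

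Among the lists, the chemotaxis genes had a median oxygen-by-light value of 0.25, at the 99.4th percentile of 10000 random lists matched on intensity, with cheB at 0.40, cheR at 0.36 and cheA at 0.34 but htr6 at -0.25 and htr2 at -0.14. This median was 0.24 in the Alexa 532 arrays and 0.0228 in the Alexa 647 arrays, 0.0613 with median centring and -0.0573 in the authors' table. Cobalamin synthesis (0.25, percentile 98.1) and aromatic amino acid synthesis (0.51, percentile 97.2, with the dim trpB and trpC among its 4 members) also lay high, and DNA replication lay low (-0.28, percentile 3.93). The medians of the other lists were -0.17 for retinal proteins, 0.01 for the citric acid cycle, -0.11 for aminoacyl-tRNA synthetases, -0.09 for purines and pyrimidines, -0.05 for glycerol and central carbon, 0.17 for the proteasome and -0.22 for DNA repair, at percentiles from 7.19 to 87.9. The percentiles describe these 4 cultures only.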

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

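Of the tests in this part, those of regional noise, of dye bias across arrays, of a reversed dye label, of dye bias in spot set 2217 and of normalization in the chemotaxis list were chosen only after the result was seen.

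mutL was flagged for dark minus light differences of opposite sign at the 2 oxygen levels. Its dark minus light difference was -0.89 at high oxygen and 0.40 at low oxygen, with opposite signs in both dye orientations, which gave a difference of 1.30. Opposite signs in both orientations were the rule that picked it from the genes ranked for this value, and so are no support. The difference was not tested, since each condition was 1 culture. mutL was above background in the knockout RNA on 4 of 8 arrays, 2 in each orientation, so neither orientation alone measures it, and in the authors' table the difference was 0.14.

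The unnamed spot set 2217 lay far below the reference in all cultures, and 3 technical explanations were set against it. With the dyes as labelled, dye bias of the probe was excluded, because the less negative of the 2 orientation means was -1.91. An error of background subtraction was excluded too, since without subtraction the least negative culture was still at -1.06. Uneven background around its spots would have lowered its neighbours, but the median of the 8 nearest spot sets was -0.0616, in a range from -0.54 to 0.32. No biological explanation was tested, because the probe has no gene name and the design holds no culture of the parent strain.

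Log ratios of the 2 arrays of a culture correlated at a mean r of -0.158, of 0.0175 with block loess and of -0.531 in the authors' table. In the main processing only the high oxygen light culture was above 0, at 0.046. Neighbouring spots of a probe correlated at a mean r of 0.489 within an array and copies on the other side of the slide at 0.171, a difference of 0.318 that regional noise on the slides would give, although noise independent between slides would bring r to 0 and not below it. Arrays of the same dye orientation correlated better than arrays of opposite orientation by 0.357, the largest difference among 35 splits (highest other 0.144), which probe-specific dye bias would give. Both explanations therefore stay open and could act together. For a reversed dye label, spot set 2217 was predicted to lie above 0 on at least 1 array, and its highest value over the 8 arrays was -1.55. This probe had been picked as the furthest past the threshold after the ratios were turned by those labels. Its single sign therefore cannot exclude a reversed label, and no unselected set of probes was checked.

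The chemotaxis list had a high median in the oxygen-by-light difference, one of 11 lists compared, with 7 of 11 members above 0. Its median was 0.24 in the Alexa 532 arrays and 0.0228 in the Alexa 647 arrays. A dye bias of the members that is the same on every array cancels within each orientation and cannot give these values. A bias that varies between arrays cannot be told apart from a response with 1 array per condition and orientation. The 8 members above background on all arrays had a median of 0.14, at percentile 95.5, which leaves a part played by dim probes open. With median centring the list median dropped to 0.0613, so the within-array normalization could account for most of it. A biological dependence on oxygen and light also stays open, untested.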

How the results depend on the processing

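The alternatives with low-setting values for saturated spots, with spot medians, with only probes above background on all arrays, with block loess outside the oxygen and light tests, with 8 arrays for the reference comparison, and all alternatives for the chemotaxis list were chosen only after the result was seen. Of 402 single-gene values that an alternative moved, 394 kept their direction and 8 did not, and 169 others could not or did not move. None of the 11 tested gene lists passed for oxygen or light under any setting. Signal over background limits the rest, since the knockout RNA of 1176 of 2573 probes was above background on all arrays. No paired analysis was possible because the labels give no replicate numbers that tie cultures together. Where a result below differed, the cause was not tested.

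The count for oxygen was 0, and it was 1 without background subtraction, 1 in the authors' table, 6 among probes above background on all arrays (2 higher, 4 lower), and 0 to 4 with 1 culture left out. The count for light was 0, and it was 80 in the authors' table (5 higher, 75 lower) and 7 among probes above background on all arrays (6 higher, 1 lower). The count against the reference was 1. It was 114 without background subtraction (45 higher, 69 lower), 0 with median centring, 573 in the authors' table (75 higher, 498 lower), 123 without the dimmest 25% (53 higher, 70 lower) and 0 with low-setting values for saturated spots. In the authors' table the median over all probes was -0.0689 against the reference and -0.093 for light, where the main fit gave 0.0147 and 0.000424. A shift of all probes therefore goes with the one-sided counts of that setting. The count against the reference was 256 among probes above background on all arrays (171 higher, 85 lower), 0 with Alexa 647 arrays alone, 3 with the intercept alone, 22 with 8 arrays and a dye term (9 higher, 13 lower), and 0 to 2 with 1 culture left out. The filter on background used the knockout signal alone and dropped probes dim in the knockout, spot set 2217 and pyrF among them. Its split can therefore lean to the higher side. Leaving out dim probes kept each remaining ratio as it was and changed only the moderation and the number of probes tested. Spot set 2217 ranged from -2.33 to -1.23 over the alternatives that kept it. With 1 culture left out the other factor was dropped from the oxygen and light fits, which left 1 culture against the other two and the spread of that pair alone, and the reference fit kept the intercept only.

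Consistent 2-fold differences numbered 3 for oxygen and 3 for light. For oxygen they numbered 0 without background subtraction, 5 with median centring, 0 in the authors' table, 0 without the dimmest 25%, 0 among probes above background on all arrays, 31 with Alexa 532 alone, 82 with Alexa 647 alone and 39 at 1.5-fold. For light the same settings gave 0, 6, 0, 0, 0, 109, 17 and 22, and block loess gave 1. The remaining split of the cultures, with 7, gave 0 without background subtraction, 4 with median centring, 0 in the authors' table, 2 with block loess and 60 at 1.5-fold. The oxygen-by-light count of 181 became 4 in the authors' table, 120 with block loess and 1 among probes above background on all arrays. The chemotaxis median of 0.25 became 0.0613 with median centring and -0.0573 in the authors' table.

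Direction turned for ppsA (oxygen, 0.0334 in the authors' table), ndk (light, 0.00447 with spot medians), sucC (light, -0.16 to 0.0698 with 1 culture left out) and gatC against the reference (-0.0901 in the authors' table, -0.0244 with spot medians, -0.30 with Alexa 647 alone, -0.12 to 0.46 with 1 culture left out).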

Other observations

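None of the values in this part was tested beyond the limma fit, and the genes were taken from lists fixed before the data were examined that held fewer than 4 named probes. For the arginine fermentation genes arcA and arcC, which yield ATP without oxygen, the low minus high oxygen difference was 0.11 ± 0.17 and 0.06 ± 0.15. The heme synthesis genes hemA and hemL lay at -0.15 ± 0.19 and -0.00 ± 0.15, and nuoL of the NADH dehydrogenase complex at 0.07 ± 0.16. The chaperone genes dnaJ and dnaK were at 0.06 ± 0.16 and 0.02 ± 0.19, and dpsA, which stores iron and protects DNA, at -0.11 ± 0.15. The ribosomal protein genes rpl12p and rpmC were at 0.12 ± 0.15 and -0.10 ± 0.15. In the dark minus light difference arcA lay at 0.16, arcC at 0.09, rpmC at 0.16, hemA at 0.11 and nuoL at -0.12. None of these genes passed the threshold in limma. dpsA was saturated on 3 of 8 arrays, nuoL on 2, and arcA, rpl12p and rpmC on 1 each, so their values are less certain than the errors show.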
